A study of Homo sapiens with 5 samples.

How the data were processed

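T84 cells were grown with or without IFN-gamma at 1000 U/ml for 6 or 18 h, and RNA was taken with Trizol, fragmented and labelled with biotin for Affymetrix arrays, per the labels' protocols. The 5 arrays fall into 3 groups by their titles: untreated (1 array, described as a pool), 6 h (2 arrays) and 18 h (2 arrays). The labels call the arrays biological replicates but do not say how the cultures were kept apart, so p-values measure the spread between these arrays, which may be partly technical.

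The deposited values are intensities per probe set on a linear scale, as whole numbers. Between 25.3% and 29.5% of them are negative, so some quantity had been subtracted before the authors deposited them. How the intensity was computed is not given in the sources used here. The mean without the top and bottom 2% of probe sets was 98.3 to 100.3 on every array, as global scaling to a common target would give, but the scaling and its target are not stated. Column medians were 36 for the array labelled untreated, 32 and 39 for the 6 h arrays, and 35 and 34 for the 18 h arrays. The value range differed: the SD of the intensities was 308, 410 and 350 on the array labelled untreated, 6 h replicate 1 and 18 h replicate 2, and 245 and 258 on 6 h replicate 2 and 18 h replicate 1. A second deposited table lists intensities of probe sets that the authors selected as induced, with a control column and 4 treated columns named by time and number.

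Probe sets were named through the platform annotation supplied with the table: 5649 of 7018 had a single gene symbol, 321 several and 1048 none, and 0 symbols needed updating. A probe set with several genes names none. The test had been planned for values that might already be logarithms. Since they proved linear with negative values, values under 20 were set to 20, 1 was added and the log2 taken. The floor of 20 was chosen after the files were seen and before any test, and floors of 0, 50 and 100 were tried as well. A fold change on this scale understates the change of dim genes, and where the lower group is at the floor on every array the intensities are given in its place, or "at least". In all, 1989 probe sets never exceeded the floor and were left out, which left 5029 probe sets and 3784 genes.

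Group means were compared by limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 5 arrays, with 2 residual degrees of freedom and a prior of 1.24, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The untreated array has no spread of its own and was assumed to vary like the treated ones. The 3 comparisons were 6 h against untreated, 18 h against untreated, and 18 h against 6 h, which is also the test of a difference between the times. The 25 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives unless stated otherwise. They were tested with limma's camera (correlation preset at 0.01), 1 probe set per gene, the one with the highest mean, and at least 3 measured members, against the 3784 tested genes (the plan had named all genes of the table, before the floor was known). Camera with an estimated correlation and fry served as alternatives. Single arrays were set against each other by a list's median log2 difference and its percentile among 10000 random lists matched on mean level, as a description of these arrays.

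Named genes are the 10 highest and 10 lowest changes of each comparison, since none passed, the 3 members of each list with the largest change at 18 h, the receptor chains and IRF1, and the first 10 entries of the authors' list. A further gene of that rule was not analysed here. Where a gene had several probe sets, their signs differed for HSPG2, NOS2, BTN3A2, CYP2A13, GABRB1, LYZ, DSC2, KCNQ1 and MUC1 in at least 1 comparison.

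No pair of arrays held copies: the largest number of equal values was 141 of 7018, and pairwise correlations on the log2 scale ran from 0.83 to 0.94. The fit was tested on simulated data for 18 h against untreated over 5029 probe sets with 200 changed. At the spread fitted here it recovered 1.75% of 8-fold changes, 24.2% of 16-fold and 50.0% of 64-fold changes, so a count of 0 leaves large changes open. With a tighter and more even simulated spread, the same number of arrays recovered 96.5% of 4-fold and 100% of 8-fold changes, with a mean of 11 false calls. The 0 thus reflects the spread between these arrays and not their number alone. For interferon genes that spread includes the gap between the 6 h arrays (CXCL10 had 41 and 1149), 1 of which opposes its label. The gap also enters the error at 18 h against untreated. On simulated data for 3784 independent genes, camera called a list of 12 genes shifted by 1 on the log2 scale and 0 others. Independent genes cannot test the preset correlation of 0.01. In the data the estimated correlation was 0.39 for the antiviral genes, 0.19 for MHC class I and 0.99 for the GTPases. It was 0.13 for the cell death genes, 0.14 for the stress genes, and -0.06 for MHC class II and for the NF-kB targets. With an estimated correlation, camera uses only the 2 residual degrees of freedom, so passing is far harder whatever the correlation. Alternatives were quantile normalization, a common median, filters on dim probe sets, the mean of a gene's probe sets, other variance priors, other thresholds, an offset of 16, the replicate number as a block, only the arrays compared, named genes only, and each treated array left out in turn. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were also used.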

Results

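Gene expression was measured in T84 cells, a human colon carcinoma line used as a model of chloride-secreting intestinal epithelium, after exposure to interferon-gamma (IFN-gamma) at 1000 U/ml. IFN-gamma is a cytokine of activated T cells and natural killer cells that acts through its receptor, JAK kinases and STAT transcription factors. There were 5 Affymetrix arrays: 1 labelled untreated and described as a pooled control, 2 at 6 h and 2 at 18 h, and the labels call the treated arrays biological replicates. Each array gave an intensity for 7018 probe sets, and 5649 of these named a single gene, 4961 genes in all. Between 39.8% and 44.0% of the probe sets of an array lay at or below an intensity of 20, which was used as a floor. The 5029 probe sets above it on at least 1 array were compared with limma. The untreated group has no replicate and each treated group has 2.

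The classic targets of IFN-gamma were read first on each array, because they bear on the labels. The chemokine CXCL10 had an intensity of 1317 on the array labelled untreated, 41 on the array labelled 6 h replicate 1, 1149 on 6 h replicate 2, and 1260 and 1399 on the 18 h arrays. The transcription factor IRF1, which STAT signalling induces, had 1086 on the array labelled untreated, 14 on the array labelled 6 h replicate 1, 907 on 6 h replicate 2, and 933 and 921 at 18 h. The peptide transporter TAP1, which loads MHC class I, had 1772, 61, 1208, 1346 and 2038 in the same order. The guanylate-binding protein GBP1 had 325, 8, 368, 452 and 405. Thus the array labelled untreated carried these genes at the level of the treated arrays, and the array labelled 6 h replicate 1 carried them near or below the floor. Both go against their labels, so each is called by its label below, and every direction drawn against either of them rests on a label that these genes oppose. The samples were kept in the groups that the labels give.

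**Figure D1:**
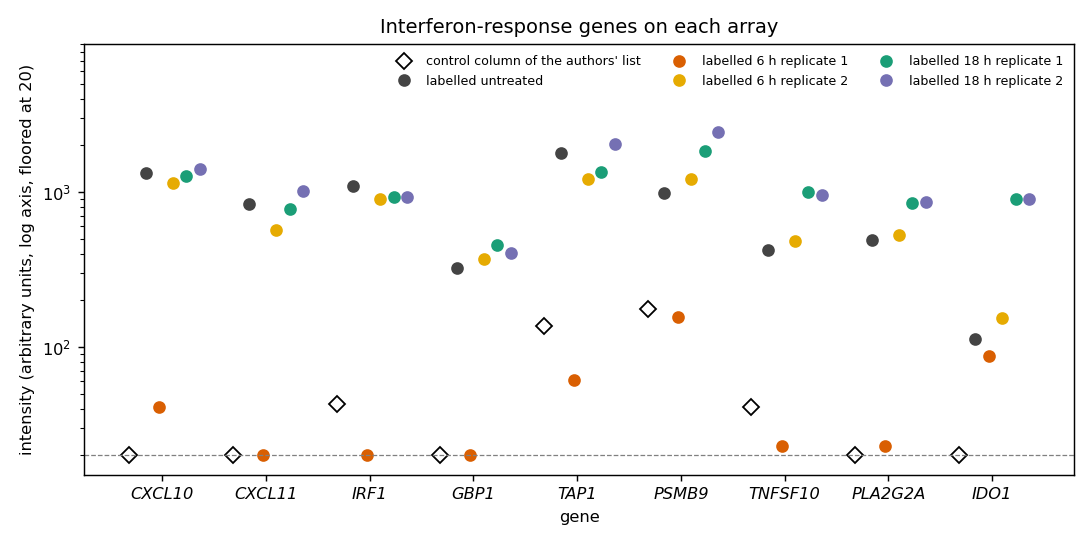
Intensity (arbitrary units, log axis, values under 20 drawn at 20) of 9 interferon-response genes, with 1 circle per array coloured by its label and a diamond for the control column of the authors' list of induced genes. For CXCL10 the array labelled 6 h replicate 1 (41) lies far under the array labelled untreated (1317), while for IDO1 only the 18 h arrays (903 and 906) stand high.

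The medians of several gene groups also differed between these single arrays. Across 24 measured type I interferon-stimulated antiviral genes, the array labelled 6 h replicate 1 lay below the array labelled untreated by a median of -1.31 (log2), with 20 members lower, and none of 10000 random lists matched on level reached so low a median. The 4 interferon-inducible GTPases had a median of -2.89 in that comparison of single arrays. The same antiviral genes on 6 h replicate 2 differed from the array labelled untreated by a median of -0.03, with 10 members higher and 13 lower. Some groups outside the interferon response had medians below 0 there as well, at -1.89 for the Wnt targets (4 of 5 below 0), -0.70 for the cell cycle genes (20 of 26) and -0.69 for the junction genes (8 of 10). Others had medians above 0, with members on both sides: 0.70 for mucin and goblet cell genes (4 of 6 above 0), 0.44 for absorptive colonocyte genes (14 of 21) and 0.48 for stress genes (13 of 20). The constitutive proteasome subunits, a set that IFN-gamma is not known to induce, had a median of 0.13 on the array labelled 6 h replicate 1 against the array labelled untreated, and the housekeeping genes also 0.13. That array stood apart from the others in many probe sets: 135 were at least 2-fold above all 4 other arrays and 242 at least 2-fold below, against 35 and 44 for the array labelled untreated, 86 and 41 for 6 h replicate 2, 28 and 20 for 18 h replicate 1, and 73 and 45 for 18 h replicate 2.

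A list of induced genes deposited by the authors holds a control column of its own. Of its entries, 97 probe sets were used here, while its title speaks of 105. Its 4 treated columns equal the value table in all 97 probe sets, whereas its control column equals the table's untreated column in 3 and the column of 6 h replicate 1 in 2. The list runs in falling order of the mean of the 18 h arrays over its own control column, from a ratio of 445.5 down to 6.67. It was therefore chosen on these samples by that ratio and is not independent evidence of induction. In 22 of its probe sets the 18 h mean reached 100, and 16 of these 22 belong to the gene groups fixed beforehand. Over these 22 the median intensity was 31 in the list's control column, 59 on the array labelled 6 h replicate 1, 372.5 on the array labelled untreated, 424.5 on 6 h replicate 2 and 800.25 for the 18 h mean. The array labelled untreated was at least 3-fold above the control column in 20 of the 22, 6 h replicate 2 in 20, and the array labelled 6 h replicate 1 in 4. Of the other 75 probe sets, whose 18 h mean is under 100, many owe their ratio to a small denominator: the control column is 3 or less in size in 57, and it is negative together with the 18 h mean in 7.

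Against that control column, the leading entries were T-cell chemokines and defence genes. The 18 h mean of CXCL10 was 1329.5 ± 98.3 (SD, n = 2), at least 66.5-fold above the control value, which lay under the floor. CXCL11, another ligand of the chemokine receptor CXCR3, reached 891 ± 164 (SD, n = 2), at least 44.55-fold. The tryptophan-degrading enzyme IDO1 reached 904.5 ± 2.12 (SD, n = 2), at least 45.2-fold, and the secreted phospholipase PLA2G2A, an antibacterial enzyme, 854 ± 15.6 (SD, n = 2), at least 42.7-fold. TRIM22 and GBP1 were at least 24.3-fold and at least 21.4-fold above. With a control value above the floor, the death ligand TNFSF10 (TRAIL) was 23.8-fold, IRF1 21.6-fold, TAP1 12.4-fold and the immunoproteasome subunit PSMB9 12.2-fold above it. Among the first 10 entries were also CLIP1 and ACRV1, with 18 h means of 46 ± 19.8 and 70 ± 42.4 (SD, n = 2), and 2 probe sets with no single gene name. No test was run on these folds, and 0 of the 97 probe sets passed the test against the table's own untreated column at either time.

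The question at 6 h was which genes the early exposure alters. As labelled, the interferon-response groups were not higher at 6 h than on the array labelled untreated: the median change was -1.47 (log2) for the 4 GTPases, -0.85 for 10 genes of JAK-STAT signalling and -0.71 for the 24 antiviral genes, of which 21 lay below 0. No group passed camera with preset correlation, and the antiviral list came closest (adjusted p = 0.285). The 2 arrays at 6 h did not share these values. The genes with the lowest mean change included IRF1, CXCL11, TAP1, CXCL10 and NOS2, the inducible nitric oxide synthase, and each lay nearer to the array labelled untreated on 6 h replicate 2 and was low on the array labelled 6 h replicate 1 (for NOS2, 526 on the array labelled untreated, 509 on replicate 2 and -22 on replicate 1). Of the 2 probe sets of NOS2, only the one given had a mean change below 0.

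Other genes differed from the array labelled untreated in the same way on both 6 h arrays. CYBA, the p22 subunit of the NADPH oxidase, had 141 on the array labelled untreated and 955 and 592 at 6 h, a log2 change of 2.41 (SE 0.39). LMAN2, a lectin of the secretory pathway, had 35 against 235 and 156, PTPRS, a receptor tyrosine phosphatase, 21 against 130 and 90, and the gap junction protein GJB1 28 against 143 and 123. The elongation factor subunit EEF1D, LAGE3 and SLC10A3 were also among the 10 highest, as were HSPG2 (-61 against 126 and 110) and CGREF1 (-11 against 135 and 167), whose values on the array labelled untreated lay under the floor. The heat shock gene HSPA6 was high on the array labelled 6 h replicate 1 alone (404, against 28 on replicate 2 and 22 on the array labelled untreated). Among the 10 lowest, EGR4 (135 against -89 and -82), PTPN5 (171 against 49 and -69), BYSL (109 against -87 and 23) and the scaffold NHERF2 (100 against 10 and 16) were lower on both, and the desmosomal cadherin DSG2 had 160 against -2 and 61. None of these passed limma's test with Benjamini-Hochberg adjustment (smallest adjusted p = 1). Adjusted over the list alone, THY1 passed within the fibroblast and endothelial markers (adjusted p = 0.0435). In all, 0 probe sets were called higher and 0 lower, with 183 of 5029 at an unadjusted p under 0.05, where 251 are due by chance.

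**Figure D2:**
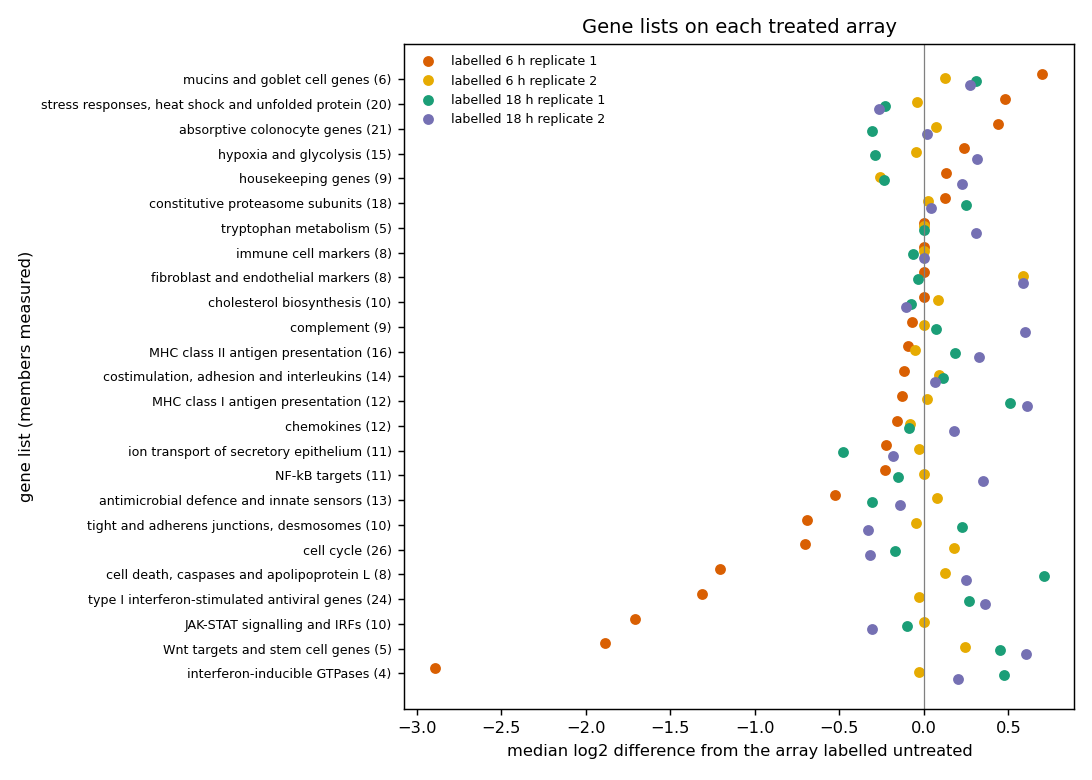
Median log2 difference from the array labelled untreated (horizontal axis) for each of the 25 fixed gene lists (vertical axis, members measured in brackets), with 1 circle per treated array. The array labelled 6 h replicate 1 lies at -2.89 for the GTPases and -1.31 for the antiviral genes, whereas 6 h replicate 2 lies at -0.03 for both.

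At 18 h against the array labelled untreated, the question was which changes the longer exposure shows. Genes of antigen presentation by MHC class I were higher as a group: 9 of 12 measured members lay above 0, with a median of 0.60 (camera adjusted p = 0.0139). The immunoproteasome subunit PSMB10 had 1354.5 ± 163 (SD, n = 2) at 18 h against 543, the non-classical class I molecule HLA-E 512 ± 4.24 (SD, n = 2) against 271, and PSMB9 2145.5 ± 421 (SD, n = 2) against 981. The type I interferon-stimulated antiviral genes were also higher, with 15 of 24 above 0 and a median of 0.25 (camera adjusted p = 0.0344). Their largest change was in the ubiquitin-like modifier ISG15, at 1057 ± 45.3 (SD, n = 2) against 176, a log2 change of 2.58 (SE 0.24), followed by IFI35 (1063.5 ± 81.3 against 433) and the exonuclease ISG20 (1661.5 ± 319 against 765). With an estimated correlation these calls were lost (adjusted p = 0.829 for class I and adjusted p = 0.845 for the antiviral genes). That test has only 2 degrees of freedom, and 0.829 was its lowest value over the 25 lists. The loss thus cannot be put down to correlation between genes. Without 18 h replicate 2 neither list passed (medians 0.51 for class I and 0.27 for the antiviral genes, adjusted p = 0.211 for each), and without 18 h replicate 1 the antiviral genes did not (median 0.36, adjusted p = 0.164), so the p-values changed more than the medians. A floor of 0 ended both calls (adjusted p = 0.0547 for class I and 0.0663 for the antiviral genes), as did fry (adjusted p = 0.721 and 0.994), and a block that crosses the replicate numbers ended the antiviral call (adjusted p = 0.0842); that floor and that block were chosen after seeing the data.

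The gene with the largest measured change at 18 h that was also above the floor on the array labelled untreated was IDO1, at 904.5 against 113, a log2 change of 2.99 (SE 0.43). The metallothionein MT1H had 385.5 ± 43.1 (SD, n = 2) against -116, CD74, the invariant chain of MHC class II, 98.5 ± 24.7 (SD, n = 2) against -35, and TGM2, the tissue transglutaminase, 166.5 ± 31.8 (SD, n = 2) against 29. PTPRS, the membrane-bound chemokine CX3CL1, the glycolytic regulator PFKFB4, LCAT, BTN3A2 and PRKCSH completed the 10 highest. The 10 lowest held the apoptosis inhibitor and mitotic protein BIRC5, at 92 ± 5.66 (SD, n = 2) against 393, a log2 change of -2.08 (SE 0.42), with PTPN5, JAK3, EGR4, PPP5C, BYSL, CYP2A13, MAPKAPK3, RBPMS and CSRP3. Of the 2 probe sets of CYP2A13, only the one used here was lower. For BIRC5 the 6 h arrays were low as well (87 and 147), so that the array labelled untreated stood alone. PTPN5, EGR4 and BYSL were among the 10 lowest at both times, and PTPRS among the 10 highest at both. For these too the array labelled untreated, which has no replicate, lay apart from both times. No probe set passed limma's test (smallest adjusted p = 0.985), with 98 higher and 125 lower at an unadjusted p under 0.05. Adjusted over the list alone, ISG15 passed within the antiviral genes (adjusted p = 0.0315), IDO1 within tryptophan metabolism (adjusted p = 0.0229) and THY1 within the fibroblast and endothelial markers (adjusted p = 0.0304), while no gene passed over all genes. That adjustment was not extended across the 25 lists. THY1, which passed at both times, lay under the floor on the array labelled untreated.

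The receptor of IFN-gamma and its JAK-STAT pathway carry the signal to the induced genes. The receptor chain IFNGR1 had 177 on the array labelled untreated, 62 and 169 at 6 h, and 113 and 69 at 18 h. The second chain, IFNGR2, had 78, then 159 and 165, then 153 and 118, and JAK1 104, then 4 and 88, then 94 and 37. Over the 10 measured genes of JAK-STAT signalling the median change at 18 h was -0.11 against the array labelled untreated and 0.48 against 6 h (8 above 0, camera adjusted p = 0.183). The 0.48 rests on the array labelled 6 h replicate 1, over which the 18 h arrays had medians of 1.68 and 0.99. Over 6 h replicate 2 they had -0.03 and -0.26. The 12 chemokines had a median of 0.04, with CX3CL1, CCL5 and CXCL3 changing most and CXCL10 and CXCL11 already high on the array labelled untreated, and the 4 GTPases 0.34, with GBP2 at 319.5 ± 3.54 (SD, n = 2) against 168 and MX2 at 175.5 ± 33.2 (SD, n = 2) against 143.

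Other immune groups also failed the test at 18 h against the array labelled untreated. The 16 genes of MHC class II had a median of 0.27, with CTSS and HLA-DRB1 next to CD74 in size of change. The 9 complement genes had a median of 0.39, with SERPING1, the C1 inhibitor, at 204 ± 9.9 (SD, n = 2) against 112, C2 at 96.5 ± 19.1 against 49 and CD46 at 307 ± 103 against 167. The 8 cell death genes had a median of 0.48, led by TNFSF10 at 975 ± 26.9 (SD, n = 2) against 420, then CASP5 and BAK1. The 11 NF-kB targets had 0.08, with TNIP1 at 384 ± 62.2 (SD, n = 2) against 208, NFKB1 at 106.5 ± 62.9 against 185, and TRAF1 at 39.5 ± 9.19 against -27. The 14 genes of costimulation and adhesion had 0.06, with TNFRSF14 at 240 ± 56.6 (SD, n = 2) against 67, LGALS9 at 688 ± 240 against 404, and CD86 near the floor. The 13 antimicrobial genes had -0.13, with lysozyme (LYZ) at 59.5 ± 7.78 (SD, n = 2) against 135, LCN2 at 102 ± 7.07 against 37, and DEFB1. In tryptophan metabolism, all 5 members lay above 0 with a median of 0.15, but HAAO and KMO moved little beside IDO1.

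No group of genes of the epithelium itself passed camera. The 21 absorptive colonocyte genes had a median of -0.13 at 18 h, with villin (VIL1), the microvillus actin bundler, at 193 ± 29.7 (SD, n = 2) against 441, and CA2 and MEP1A also lower. The 11 genes of ion transport had -0.28, and SLC12A2 (the basolateral chloride cotransporter), the potassium channel KCNQ1 and the guanylin receptor GUCY2C had 202 ± 62.2, 70 ± 25.5 and 192 ± 17 (SD, n = 2) against 370, 151 and 340. Of the 2 probe sets of KCNQ1, only the one given was lower. The 6 mucin and goblet cell genes had 0.30, with MUC1 at 161.5 ± 0.707 (SD, n = 2) against 66, then MUC2 and TFF3. The 10 junction genes had -0.09, with CTNNB1 at 477 ± 77.8 (SD, n = 2) against 210, DSG2 and DSC2. Wnt targets (5 genes, 0.55, with EPHB3, CCND1 and SOX4), cell cycle (26 genes, -0.26, with BIRC5, MCM2 and CCNB1), cholesterol biosynthesis (10 genes, 0.03, with FDPS, SC5D and SQLE), hypoxia and glycolysis (15 genes, -0.02, with PFKFB4, HK2 and VEGFA) and stress responses (20 genes, -0.18, with ASNS, EGR1 and JUN) did not pass either. The constitutive proteasome had 0.08, with PSMB3, PSMA1 and PSMC2 leading, and the housekeeping genes -0.03, with the transferrin receptor TFRC at 297.5 ± 64.3 (SD, n = 2) against 1072, then SDHA and TBP. Markers of other cell types had small medians: the 8 immune cell markers had a median of 0.03, with CD79A, PTPRC and CD3E leading, and the 8 fibroblast and endothelial markers 0.16, with THY1 (79 ± 5.66 against -17), ACTA2 and PDGFRB.

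The comparison of 18 h with 6 h asks whether the response differs between the times. As labelled, 6 of the 25 lists were higher at 18 h and 1 was lower. The lists are not fully separate, since MX2 is a member of both the GTPase list and the antiviral list. The antiviral genes had a median of 0.83, with 24 of 24 members above 0 (camera adjusted p = 1.38e-08), and included ISG15 (3.65-fold). Set against 6 h replicate 2 alone, 19 of the 24 were higher on 18 h replicate 1 and 17 on 18 h replicate 2. TRIM22 and IFI35 were far lower on the array labelled 6 h replicate 1 (26 and 118) than on 6 h replicate 2 (229 and 656), against 498 and 1006 on 18 h replicate 1. MHC class I had a median of 0.77 with 10 of 12 above 0 (camera adjusted p = 0.000805), and MHC class II 0.44 with 13 of 16 (camera adjusted p = 0.00269). The GTPases had 2.03 with 4 of 4, the cell death genes 0.90 with 7 of 8, and the NF-kB targets 0.23 with 8 of 11 (camera adjusted p = 0.0268 for each). The stress genes were lower, with a median of -0.63 and 18 of 20 below 0 (camera adjusted p = 0.00269). None of the 7 calls held with an estimated correlation: adjusted p = 0.637 for the GTPases and adjusted p = 0.575 for the other 6. That test has only 2 degrees of freedom, and 0.575 was its lowest value over the 25 lists. For MHC class II and the NF-kB targets the estimated correlation was negative (-0.06 for each), so correlation cannot account for their loss.

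The calls were fitted again with each treated array left out. Without the array labelled 6 h replicate 1, the antiviral genes (median 0.43, adjusted p = 0.000204), MHC class I (0.46, adjusted p = 0.00116), MHC class II (0.36, adjusted p = 0.0176) and NF-kB targets (0.33, adjusted p = 0.0147) still passed camera with preset correlation. The GTPases (0.35, adjusted p = 0.0645), cell death genes (-0.03, adjusted p = 0.482) and stress genes (-0.10, adjusted p = 0.975) did not. On that array the stress list held DNAJB1 at 1612, FOS at 604, HSPA6 at 404 and EGR1 at 369, against 566, 71, 28 and 74 on 6 h replicate 2. Without 6 h replicate 2, MHC class II (0.42, adjusted p = 0.0540) and the NF-kB targets (0.22, adjusted p = 0.376) no longer passed, at medians close to those of the full fit. Without 18 h replicate 1, the GTPases (1.89) and cell death genes (0.92, adjusted p = 0.424 for each), NF-kB targets (0.35, adjusted p = 0.0708) and stress genes (-0.80, adjusted p = 0.0542) no longer passed, although their medians stayed about as large or larger. Without 18 h replicate 2, the GTPases (2.16, adjusted p = 0.181), cell death genes (0.84, adjusted p = 0.134) and MHC class I (0.67, adjusted p = 0.0680) also kept most of their median and did not pass. The medians of MHC class II (0.15) and stress genes (-0.46, adjusted p = 0.0680 for each) and NF-kB targets (0.14, adjusted p = 0.177) shrank with it. The antiviral genes passed in each case (medians 1.55, 0.77 and 0.91), but with an array left out its time has 1 array and the remaining pair of the other time gives all the spread.

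Some genes set both 18 h arrays apart from the other 3 arrays, whichever label those carry. Such a split is not particular to the 18 h pair, which at a limit of 2-fold had 15 probe sets higher and 7 lower. Pairs of unlike labels had more (45 and 24 for 6 h replicate 1 with 18 h replicate 2) or fewer (9 and 3 for 6 h replicate 2 with 18 h replicate 2). IDO1 had 903 and 906 at 18 h against 88 and 153 at 6 h and 113 on the array labelled untreated. ISG15 had 1025 and 1089 against 265 and 315, and 176. TGM2 had 189 and 144 against -8 and -11, and 29, and CD74 116 and 81 against values all under 0. VIL1 was lower (214 and 172 against 387 and 466, and 441), as was LLGL1, a regulator of epithelial polarity (26 and 37 against 143 and 112, and 111). HLA-E, at 1.93-fold, had 509 and 515 against 253 and 277, and HLA-F, chosen after its values were seen, 846 and 1011 against 473 and 465. Within their lists alone, IDO1 (adjusted p = 0.0125), ISG15 (adjusted p = 0.0464) and CD74 (adjusted p = 0.0405) passed limma's test. That adjustment covers 1 list in 1 comparison and was not extended across the 25 lists and 3 comparisons. For CD74 both 6 h values lay under the floor, so the floor gave that pair no spread.

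**Figure D3:**
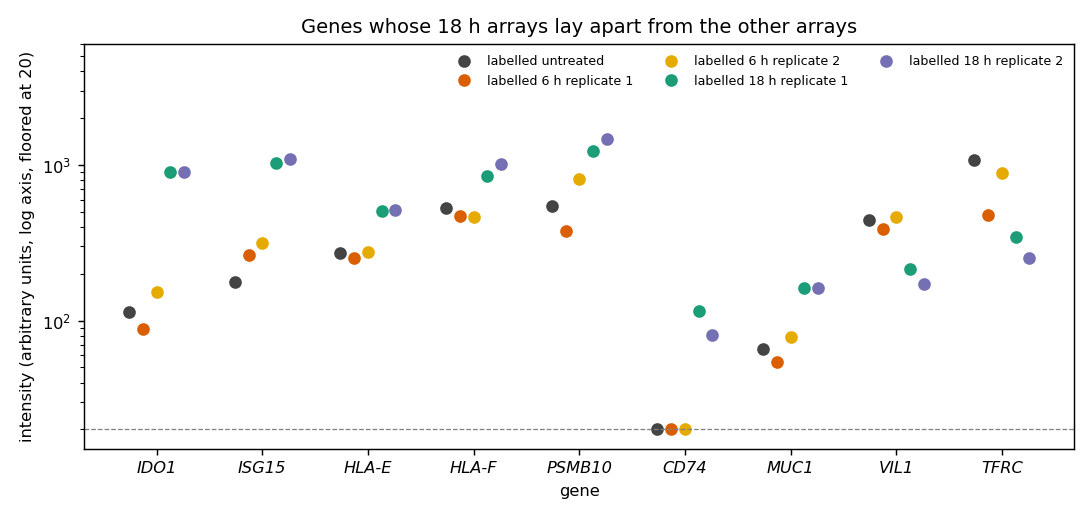
Intensity (arbitrary units, log axis, values under 20 drawn at 20) of 9 genes on the 5 arrays, 1 circle per array coloured by its label, chosen after the values were seen. For IDO1 the 18 h arrays stand at 903 and 906 and the other 3 between 88 and 153, and for VIL1 they stand at 214 and 172 and the other 3 between 387 and 466.

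The rest of the 10 highest changes from 6 h to 18 h were TNFSF10, MT1H, CXCL11, PLA2G2A, IRF1, GABRB1, TRIM22 and TAP1, and 6 of these (TNFSF10, CXCL11, PLA2G2A, IRF1, TRIM22 and TAP1) have a low value on the array labelled 6 h replicate 1 only. TNFSF10, for example, had 994 and 956 at 18 h, 481 on 6 h replicate 2 and 23 on the array labelled 6 h replicate 1. The 10 lowest held LLGL1, KRT7, HSPG2, CYP11B1, GABRQ, the malic enzyme ME1 (65 and 31 against 180 and 125), ABLIM1, RBPMS, EGR1 and ABL2. No probe set passed limma's test (smallest adjusted p = 0.940), with 112 higher and 105 lower at an unadjusted p under 0.05. The calls at 6 h and 18 h against the array labelled untreated shared 0 probe sets, since neither time had a call. At an unadjusted p under 0.05, 41 probe sets were higher and 60 lower at both times, against means of 56.2 and 56.0 over 100 simulations of unchanged groups that share the untreated array, and 1.66 and 2.44 for independent lists. The shared untreated array alone thus gives overlaps of that size.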

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

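Lists whose effects at 6 h and 18 h differed by the test of the difference itself are given first. In the weighing that follows, the tests of the label pattern and of the stress genes were chosen only after the result was seen, and those of the shared axis were written down before their values were computed.

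The list tests at 18 h against 6 h passed for 7 of 25 lists, with median log2 differences of 2.03 for the interferon-inducible GTPases, 0.77 for MHC class I, 0.44 for MHC class II, 0.83 for the antiviral genes, 0.90 for the cell death genes, 0.23 for the NF-kB targets and -0.63 for the stress genes. None of the 7 held with an estimated correlation (adjusted p = 0.637 for the GTPases and 0.575 for the other 6). That test has only 2 degrees of freedom, and 0.575 was its lowest value over the 25 lists. Without 6 h replicate 1 the medians became 0.35 for the GTPases, -0.03 for the cell death genes and -0.10 for the stress genes, and these 3 calls ended. No single probe set passed limma's test, with 217 at an unadjusted p under 0.05. No group has the 4 arrays that a test for an outlying sample needs.

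The first pattern is that interferon genes were high on the array labelled untreated and low on the array labelled 6 h replicate 1. An array-wide difference in brightness or scaling is argued against by the housekeeping genes, at a median of 0.13 between these arrays (MAD 0.63), and the constitutive proteasome, also 0.13 (MAD 0.52), where the antiviral genes differed by -1.31. A culture at 6 h that did not respond, with every other label right, is argued against as the whole cause, since the antiviral genes on 6 h replicate 2 would then exceed the array labelled untreated and their median was -0.0274. An exchange of the labels of these arrays before the values were made stays open without support from a test: the percentile of 0 among matched random lists, for the antiviral genes between these arrays, restates the values that raised this explanation. Separate mistakes on each array stay open too, and an exchange alone does not account for the control column of the authors' list, which equals neither array, so the labels may not be settled from these values.

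The second pattern is that stress and immediate early genes were high on the array labelled 6 h replicate 1, by a median of 0.77 over 6 h replicate 2. A wider range of values on that array could lift bright genes. The list's median lay at percentile 99.94 among lists matched on level, and at percentile 95.75 after quantile normalization, where the median was 0.32, so range and a real difference cannot be told apart: the percentile stays high but under the bound written for excluding it. For 6 h of IFN-gamma as the cause, 6 h replicate 2 should also exceed the 18 h arrays; its list median lay at percentile 71 against 18 h replicate 1 and at percentile 94.95 against 18 h replicate 2, which leaves the question open with 1 array a side. The array labelled 6 h replicate 1 also held the interferon genes low, as in the first pattern. Over the 24 antiviral genes, 6 h replicate 2 lay above it by a median of 1.26 (log2), with 19 members higher and 3 lower. An effect of IFN-gamma on its stress genes would thus have come without that response. How the cultures were handled was not tested.

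The third pattern is that the arrays of a time differed along a shared axis. On it, 6 h replicate 1 lay on the side of 18 h replicate 2, and 6 h replicate 2 on that of 18 h replicate 1. Each 6 h array had its highest log2 correlation with that 18 h array (0.875 and 0.936). However, 18 h replicate 2 lay closer to 18 h replicate 1 (0.920) than to either 6 h array. Of the 6 h arrays, it lay slightly closer to 6 h replicate 2 (0.883) than to 6 h replicate 1 (0.875). On intensities that order was reversed (0.912 and 0.917). Of 222 probe sets with a mean of at least 1000, 184 were higher both on 6 h replicate 1 than on 6 h replicate 2 and on 18 h replicate 2 than on 18 h replicate 1, and the median differences over the 222 were 1.04 and 0.52 (log2). Range alone is argued against, since the correlation across probe sets between the differences of the 6 h and the 18 h pair was -0.29 before and -0.27 after quantile normalization. Replicate numbers crossed between the times are allowed by that value of -0.27. It gives them no separate support, since the same value and bound were used to judge range. A shared day, labelling or scanner setting would act in the same way. No biological explanation was tested, since no group of the design follows this axis.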

How the results depend on the processing

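Floors of 0, 50 and 100, the crossed block and the setting without the arrays that oppose their labels were chosen after seeing the data. All counts of called probe sets stayed at 0 in each comparison under every alternative run, as did the overlap and the calls among the authors' list. The filter at the 25th percentile removed nothing. The number of lists higher at 18 h against untreated, 2, became 0 with an estimated correlation, 0 with fry, 0 with a floor of 0 and 1 with the crossed block, and ran from 0 to 3 with single arrays left out. At 18 h against 6 h, 6 higher and 1 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry. The higher lists became 4 with a floor of 0, 8 with 50, 7 with 100, and 5 with a common median or the mean of a gene's probe sets, with 1 lower in each. A floor of 0 ended the cell death and NF-kB calls (adjusted p = 0.0810 for each), a floor of 100 the cell death call (median 0.05, adjusted p = 0.306), a common median the NF-kB call (adjusted p = 0.0553) and the mean of probe sets the cell death call (adjusted p = 0.0663). The counts at 18 h against 6 h ran from 1 to 5 and from 0 to 1 with single arrays left out. At 6 h against untreated, 0 lower lists became 0 to 3 with single arrays left out, the 3 without 6 h replicate 2. Leaving out the arrays that oppose their labels was run only at 18 h against 6 h. The array labelled untreated enters neither group there and has no spread of its own. The medians of the called lists therefore equalled those without 6 h replicate 1 alone by construction, and are no second check. The stress genes then had a median of -0.10, so their lower value was not kept. The antiviral genes had 0.43, with 1 array left at 6 h.

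The 6 h and 18 h arrays share replicate numbers, and the pair differences correlate at -0.29 on the log2 scale and -0.67 on intensities. These values give no sign that equal numbers pair the arrays. They cannot settle it, since the 6 h difference includes an array that opposes its label. With the replicate number as a block and the untreated array midway, 0 probe sets were called and 2, 6 and 1 lists as before. With the untreated array as number 1, changes at 18 h against untreated became negative for CXCL11 (-1.21), CXCL10 (-1.22), PLA2G2A (-0.31), GBP1 (-0.60), MX2 (-0.27) and TBP (-0.34). With the crossed block, 0 probe sets were called. With single arrays left out, the change crossed 0 for HAAO at 18 h against untreated (-0.014 to 0.63), for CXCL10 at 18 h against untreated (-0.064 to 0.087), for ACRV1 at 18 h against untreated (-0.95 to 0.35), for CXCL11 at 18 h against untreated (-0.11 to 0.27) and for DSC2 at 18 h against untreated (-0.74 to 0.23). The cause was not tested for any of these. The signal limits dim genes: values under 20 carry no order.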

Other observations

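The genes named here were chosen after their values were seen. In all, 15 probe sets were at least 2-fold higher on both 18 h arrays than on all 3 other arrays, and 7 at least 2-fold lower. Besides IDO1, ISG15, CD74, TGM2, MT1H and 1 of the 2 probe sets of MUC1, the higher ones included SMPD1, the lysosomal acid sphingomyelinase, at 199 ± 7.07 (SD, n = 2) against 44 to 90, DGKD, a diacylglycerol kinase, at 97 ± 5.66 against 23 to 46, and PTK6, an epithelial tyrosine kinase, at 172 ± 102 against -67 to 38. FZD5, a Wnt receptor, had 91 ± 14.1 where the other 3 arrays lay under the floor. The lower ones were AKR1C1, CACNA2D1, DUSP4, GABRQ, LLGL1, SLC26A2, a sulfate transporter, and TPMT, a thiopurine methyltransferase, which had 10 ± 4.24 against 44 to 49. None of these is called by limma. By the same rule, the other pairs of arrays gave 45 higher and 24 lower for 6 h replicate 1 with 18 h replicate 2, 36 and 33 for 6 h replicate 2 with 18 h replicate 1, 15 and 5 for 6 h replicate 1 with 18 h replicate 1, 9 and 3 for 6 h replicate 2 with 18 h replicate 2, and 6 and 8 for the 6 h pair. The array labelled untreated gave 14 and 28 with 6 h replicate 1, 23 and 17 with 6 h replicate 2, 6 and 7 with 18 h replicate 1, and 7 and 14 with 18 h replicate 2.

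Some genes of growth, picked after their values were seen, were low on the array labelled 6 h replicate 1. MYC, a driver of proliferation, had 20 there against 332 to 447 on the other arrays, cyclin D1 (CCND1) 98 against 365 to 630, and the replication clamp PCNA 271 against 705 to 898. The 26 cell cycle genes as a list lay above 6 h replicate 1 by medians of 0.72 on 6 h replicate 2, 0.37 on 18 h replicate 1 and 0.16 on 18 h replicate 2. On 6 h replicate 1 the list lay at -0.70 against the array labelled untreated. At 18 h the list also had a median of -0.26 against the array labelled untreated (19 of 26 below 0), which did not pass camera. The inflammatory chemokine CXCL8 had 275 on 6 h replicate 1 against 38 to 68, and the trefoil peptides TFF1 and TFF3 1075 and 1046 against 556 to 701 and 369 to 621.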
